A study of Mus musculus with 6 samples.

How the data were processed

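The series holds 6 libraries of polyadenylated RNA from cultured mouse gastric corpus organoids, 3 with Erbb2 overexpression and 3 with an empty vector. RNA was extracted with a column kit, libraries were made with the Illumina TruSeq mRNA assay and sequenced on a NovaSeq instrument, per the labels' protocols. STAR, featureCounts and the mouse assembly GRCm39 are named in the submitters' processing notes; the versions, the gene annotation and the strand setting are not given in the sources used here. The values are raw read counts per Ensembl gene as deposited, whole numbers under a column for matched counts per the file headers, with 1 table per library and 25528 genes in each. Total counts lay between 18735853 and 22767455. No pair of tables was identical, and libraries of the same group differed far beyond sampling noise, with chi-square values between 34.9 and 132 per degree of freedom. The strand setting was not given, so a gene and its antisense partner cannot be told apart.

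Gene symbols were taken by Ensembl ID from a mouse annotation table and matched 25424 of the 25528 IDs. The 104 IDs without a symbol held between 0.120% and 0.219% of the counts and stayed in the tests. The reference annotation given was of an earlier assembly, so that it served for names, gene order, transcript length and GC content, and coordinates are not reported. Groups and replicate numbers came from the sample titles. The labels do not say whether libraries of a group came from separate cultures, animals or lines. P-values therefore measure the spread between these libraries, or within pairs of them where a fit is paired, and this may be technical.

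Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 12593, and scaled by the trimmed mean of M values (TMM). Differences were tested with the two-sided quasi-likelihood F test, with robust moderation and the current form of the fit, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM are counts divided by the TMM-scaled library size and multiplied by 1000000, given as mean and SD over 3 libraries. The design fixed before the data were examined had the group as its single term. A fit with the replicate number as a block was among the alternatives fixed with it. Its p-values measure the spread of the differences within pairs and leave out the spread between the numbers.

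Whether the shared numbers pair the libraries was checked by the correlation, across genes, of deviations from the group means of log2 CPM. It was 0.333, 0.660 and 0.707 for replicates 1, 2 and 3, and each library correlated best with the library of its own number in the other group. The labels give only the numbers, so that the pairing rests on this check of the same counts that were tested. With 3 libraries per group few matchings are possible, and the matching by number can come out best by chance. The check is therefore weak. In the results, gene values are from the fit with the block and camera values from the fit without it, unless stated otherwise.

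Gene lists were fixed before the data were examined, 33 in number, of which 29 had at least 4 tested genes. These were tested with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list and with fry. Erbb2 is in none of the lists. Muc6, a member of the mucous neck list, was not analysed here. Within each list p-values were also adjusted over the list alone. The genes named were chosen by a rule fixed at the same time. It takes Erbb2, the 6 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not a predicted-gene name, up to 4 members of each list with the smallest p and at least the first 2, and any checkpoint ligand or driver gene. A list member that the rule names is not reported here. Without the block 0 genes met the condition for the largest changes, so that part of the rule and the order of list members were taken from the fit with the block, where 140 genes met it. Of the 389 genes called with the block, 150 had groups that did not overlap; among all genes tested 8.75% did, where chance gives 10% for 3 against 3 libraries.

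Alternatives were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the replicate block, each library left out in turn, mitochondrial genes and Erbb2 removed, and the earlier form of the quasi-likelihood fit. After the data were seen the same alternatives were added to the fit with the block, with each pair of libraries left out in turn and offsets for GC content and transcript length. DESeq2 gave no adjusted p for 250 genes, which were left out of its counts.

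The procedures were tested on simulated counts drawn from the means, library sizes and dispersions of the 12593 genes for the comparison of Erbb2 overexpression with control. Each replicate number had its own means, and dispersions came from the fit with the block, so the pairing was built into the simulated counts. Better recovery with the block was thereby set in advance and does not bear on whether the real libraries are paired. With the block, edgeR recovered 73.1% of genes changed 1.5-fold (49 genes), 85.1% at 2-fold (57) and 100% at 4-fold (66). It also called 28 of 12297 unchanged genes. Beside the genes recovered, these 28 were a larger share of the calls than the adjusted p threshold allows. Calls with the block may therefore hold more false ones than the threshold implies. Without the block, 0%, 23.9% and 66.7% were recovered and 0 unchanged genes were called. Camera at the preset correlation recovered 6 of 6 lists of random genes shifted 1.32-fold in both fits. Camera with an estimated correlation and fry were not run on the simulated counts, so that their power was not measured. The counts were drawn gene by gene, so that the simulation does not measure false calls among lists whose genes vary together. With labels exchanged among the real libraries camera called up to 11 lists without the block and 12 with it. Such exchanges keep part of the real grouping, so these lists cannot all be read as false calls. Figures were drawn with matplotlib 3.10.9.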

Results

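RNA sequencing was done on mouse gastric corpus organoids, which are epithelial structures grown in culture from the acid-secreting body of the stomach. The organoids carried either an overexpression construct for Erbb2 or an empty vector. Each of the 2 groups had 3 libraries, numbered 1 to 3 in both. The deposited tables gave read counts for 25528 genes, and the totals ran from 18735853 counts in control replicate 2 to 22767455 in Erbb2 replicate 3. After genes with few counts were removed, 12593 genes were tested. The title of the series concerns the response of organoid-derived tumours to immune checkpoint inhibition, and the comparison measured here was between the cultured organoids of both genotypes.

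Erbb2, which encodes a receptor tyrosine kinase of the epidermal growth factor receptor family, was higher in the overexpressing organoids in each of the 3 pairs of libraries. Its level was 325 ± 35.0 CPM (counts per 1000000 scaled counts; SD, n = 3) in the overexpressing group (gene ENSMUSG00000062312) and 139 ± 21.9 CPM in the controls, and the groups did not overlap. The fitted log2 fold change was 1.23 with a standard error of 0.15 without a block (edgeR, adjusted p = 0.64 over all genes). With the replicate number as a block the fold was 2.35 and the adjusted p was 3.47e-05. Counts per gene do not separate transcripts of the introduced sequence from those of the endogenous gene. The labels do not say which species or part of Erbb2 the construct holds. Its transcripts may be counted only in part, so that the fold need not be the degree of overexpression. Of the 8 tested genes that lie next to Erbb2 in the genome, 0 differed, also when adjusted over the list alone; Stard3 had a log2 fold change of 0.19 and Pgap3 one of -0.16 with the block (adjusted p = 0.317 and 0.526 in edgeR).

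**Figure D1:**
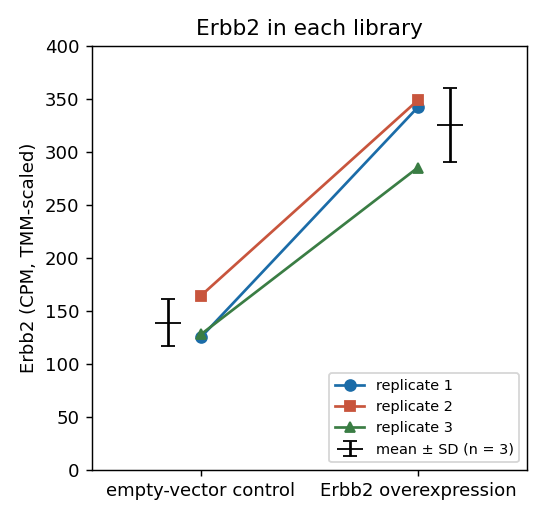
Erbb2 in CPM (vertical axis, scaled by library) in the 3 empty-vector control and 3 Erbb2 overexpression libraries, with lines joining libraries of the same replicate number and bars giving the mean and SD of each group. The overexpressing libraries lie between 285 and 349 CPM and the controls between 125 and 164 CPM.

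With the replicate number as a block, 298 genes were higher and 91 were lower in the overexpressing organoids, and 79 and 27 of these changed at least 2-fold. All 389 moved in the same direction in 3 of 3 pairs. They were chosen by the fit to these same pairs, which favours such agreement, so it is no separate support. Without the block, edgeR called 0 genes higher and 0 lower, with 419 genes at an unadjusted p under 0.05, while limma voom called 0 and DESeq2 called 28 higher and 6 lower. The first principal component, which held 57.8% of the variance, parted both libraries of replicate 3 from the other 4. Mitochondrial transcripts held 8.01%, 11.1% and 6.34% of counts in Erbb2 replicates 1, 2 and 3 and 8.14%, 10.6% and 8.05% in the controls. The number of calls with the block also depended on which pair was left out. It was 173 higher and 40 lower without replicate 1, 122 and 24 without replicate 2, and 769 and 320 without replicate 3. Fold changes, standard errors and adjusted p-values of genes below are from the fit with the block unless stated otherwise. Camera values, also those with an estimated correlation, are from the fit without the block unless the block or a left-out pair is named. The verbs of change below refer to the fit with the block, and each gene named as changed missed the threshold over all genes in edgeR without it. Of the 49 genes named as changed besides Erbb2, 32 missed it with the block when some pair was left out, 23 without replicate 1, 25 without replicate 2 and 1 without replicate 3. Leaving out a pair also leaves fewer libraries to measure the spread, so that p-values rest more on the spread shared across genes. Such changes in calls therefore mix lost power with dependence on a pair.

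**Figure D2:**
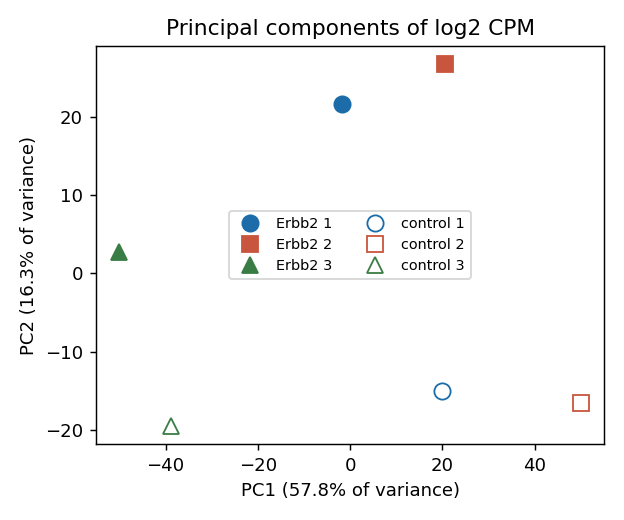
The first principal component (horizontal axis, 57.8% of the variance of log2 CPM) against the second (vertical axis, 16.3%) for the 6 libraries, with filled symbols for Erbb2 overexpression, open symbols for control and a symbol shape for each replicate number. The first component parts replicate 3 from the others, and the second places each overexpressing library above the control of its number. On the first component each overexpressing library also lies lower than the control of its number, on the side of replicate 3.

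Among genes with the largest changes whose groups did not overlap, Mgam2-ps, annotated as a pseudogene of a maltase-glucoamylase, rose 38.1-fold from 0.741 ± 1.04 CPM to 30.7 ± 4.57 CPM (SD, n = 3). Reads of a pseudogene can be shared with its parent gene, so this level is uncertain. The fold also rested on single libraries: control replicate 3 was at 1.94 CPM and the other controls at 0.232 and 0.0563 CPM, and the log2 fold change of 5.25 became 7.67 without replicate 3. Its adjusted p was 0.259 without replicate 1, 0.0978 without replicate 2 and 0.182 with the earlier form of the fit. Heph, the ferroxidase hephaestin, rose 20.3-fold to 4.77 ± 2.69 CPM. Sall1, a zinc finger transcription factor, rose 6.33-fold and Cand2, a regulator of cullin ubiquitin ligases, 5.66-fold. Gstp3, of the glutathione S-transferases, rose 4.10-fold and Clca3b, of the chloride channel accessory proteins, 3.97-fold; both belong to families of similar genes that can share reads. Without replicate 3 the log2 fold change of Cand2 moved from 2.50 to 3.47 and that of Gstp3 from 2.03 to 1.39 (adjusted p = 0.0514). Cckar, the cholecystokinin A receptor, fell 4.48-fold from 35.0 ± 16.6 CPM to 7.51 ± 2.36 CPM. Baiap2l2 fell 3.41-fold, the small heat shock protein Hspb8 3.32-fold, the proton channel Otop2 2.61-fold, the zinc finger gene Zfp354c 2.61-fold and the matrix protein Chad 2.55-fold. Adjusted p-values of these genes lay between 0.000115 for Heph and Cckar and 0.0374 for Zfp354c (edgeR with the block).

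Of 12 tested ErbB receptors and ligands other than Erbb2, 2 rose and 0 fell, and 5 rose when adjusted over the list alone. Ereg, which encodes the ligand epiregulin, rose 5.92-fold from 3.13 ± 4.45 CPM to 16.8 ± 14.4 CPM (adjusted p = 0.00485). The groups overlapped, with controls at 0.556, 0.563 and 8.26 CPM and overexpressing libraries at 9.42, 7.59 and 33.4 CPM for replicates 1, 2 and 3. The pairs gave log2 fold changes of 3.87, 3.55 and 2.01, and the fit without replicate 3 gave 3.93. Btc, the ligand betacellulin, rose 1.42-fold (adjusted p = 0.0276). Egfr had a log2 fold change of 0.68 (SE 0.16, adjusted p = 0.0809 in edgeR) and Errfi1, a feedback inhibitor of these receptors, one of 0.25 (adjusted p = 0.0983). As a set the list stood higher than the other genes (camera, adjusted p = 0.000143 without the block), and the adjusted p was 0.146 with an estimated correlation. Of 20 MAPK feedback and target genes, 5 rose and 0 fell, and 11 rose when adjusted over the list alone (1, Dusp4, without the block). Ier3 rose 1.70-fold, the ephrin receptor Epha4 1.62-fold, the MAPK phosphatase Dusp4 1.57-fold and the cyclin Ccnd1 1.40-fold. The camera test of this list gave an adjusted p of 6.22e-07, against an adjusted p of 0.146 with an estimated correlation. Of 16 AP-1 and immediate early genes, 1 rose, Myc, by 1.33-fold (adjusted p = 0.0124), and adjusted over the list alone 1 rose and 1 fell; Jun had a log2 fold change of -0.28 (adjusted p = 0.0955). Of 15 targets of FOXO factors that AKT signalling lowers, 0 changed over all genes and 1, Irs2, when adjusted over the list alone (log2 fold change 0.58, adjusted p = 0.0682 over all genes); Cdkn1b stood at -0.23. With all libraries neither of the last 2 lists passed camera (adjusted p = 0.948 and 0.491). The AP-1 list passed as higher without control replicate 2 or Erbb2 replicate 3 (0.000706 and 0.0101) and as lower without control replicate 3 (0.0277), and the FOXO list passed as higher without Erbb2 replicate 3 (0.0410).

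Cell-type genes moved in several lists. Of 14 mucous neck cell and metaplasia markers, 4 rose and 0 fell, and 6 rose when adjusted over the list alone. Tff2, a secreted trefoil peptide, rose 1.88-fold from 55.3 ± 32.3 CPM to 105 ± 62.0 CPM, Agr2, a disulfide isomerase of mucous cells, 1.51-fold, Nupr1 1.43-fold and the chloride channel Cftr 1.67-fold (camera, adjusted p = 0.000976, or adjusted p = 0.146 with an estimated correlation). Of 15 pit cell markers 13 were tested. Muc5ac, named outside the rule, was below the filter, with 2, 56 and 8 counts in Erbb2 replicates 1, 2 and 3 and 1, 0 and 2 in the controls. Among the 13, 3 rose and 0 fell. Adjusted over the list alone 5 rose and 2 fell, and 1, Psca, rose without the block. Aldh3a1, an aldehyde dehydrogenase, rose 2.07-fold (adjusted p = 0.000115), Psca 2.05-fold from 72.6 ± 8.40 CPM to 150 ± 25.8 CPM, and Mucl3 1.47-fold, while Gkn2 had a log2 fold change of 2.03 (SE 0.57, adjusted p = 0.0825). Gkn2 was low, at 0.310 ± 0.141 CPM in controls and 1.39 ± 1.04 CPM in overexpressing organoids, and its groups overlapped. The pit cell list had a median log2 fold change of -0.03 and a mean of 0.44 with the block, so that its median and its test differed in sign (camera higher, adjusted p = 0.00723, or adjusted p = 0.461 with an estimated correlation and 0.164 on voom values). Of 9 squamous forestomach genes, 2 rose, also when adjusted over the list alone (1, Sprr1a, without the block). The cornified envelope genes Sprr1a and Ivl rose 2.03-fold and 2.28-fold, Sprr1a from 260 ± 55.6 CPM to 528 ± 114 CPM (camera, adjusted p = 2.56e-06, or adjusted p = 0.146 with an estimated correlation).

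Of 13 parietal, 12 chief and 17 enteroendocrine cell markers, 5, 4 and 11 had too few counts to be tested. They reached at most 0.732, 0.516 and 0.901 CPM in any library. Among them, named outside the rule, were the parietal marker Atp4b with 0 counts in each library and the chief cell marker Lipf with at most 2. Of 8 tested parietal cell markers, 1 fell, also when adjusted over the list alone: the potassium channel gene Kcnj15, 1.62-fold (adjusted p = 0.00378). Aqp4, a water channel, was at 7.43 ± 8.13 CPM in controls and 78.1 ± 26.0 CPM in overexpressing organoids, and its adjusted p was 0.174 with the block and 0.0307 when adjusted over the list alone without it. With all libraries the parietal list passed camera as higher with the block (adjusted p = 0.0379, or adjusted p = 0.477 with an estimated correlation) and not without it (adjusted p = 0.161). Its median log2 fold change with the block was 0.09 and its mean 0.55, with 5 genes above 0 and 3 below. The largest values were those of Aqp4 (3.57) and Slc26a9 (1.33), and neither passed over all genes (adjusted p = 0.174 and 0.394 in edgeR). Without the block it passed when control replicate 2 or 3 was left out (adjusted p = 0.0368 and 0.00843), and with the block it did not pass with no filter on low counts (0.290), with offsets for GC content and length (0.0684) or on voom values (0.171). Of 8 chief cell markers, 0 changed over all genes and 1, Clps, fell when adjusted over the list alone; Pgc, the pepsinogen C gene, was at 79.4 ± 23.2 CPM in controls and 60.3 ± 8.96 CPM in overexpressing organoids. Of 6 enteroendocrine markers, 0 changed, also adjusted over the list alone, with Chgb at a log2 fold change of 1.54 (SE 0.86) and Cpe at 0.14. Chgb was low, at 0.328 ± 0.203 CPM in controls and 1.17 ± 1.52 CPM in overexpressing organoids, with 2.89 CPM in Erbb2 replicate 2. Of 18 Wnt target and gastric stem cell genes, 1 fell, also adjusted over the list alone: the transcription factor gene Sox2, by a log2 fold change of -0.48 (SE 0.09, adjusted p = 0.0144); Runx1 stood at -0.24. With all libraries this list did not pass camera (adjusted p = 0.161, or 0.0563 with the block), but with the block it passed as lower with offsets for GC content and length (0.0321) and on voom values (0.0133). Of 10 intestinal genes, 1 rose and 2 when adjusted over the list alone. This was Cdx2, an intestinal transcription factor gene, which rose 3.66-fold from 0.975 ± 1.21 CPM to 3.59 ± 1.41 CPM, with a log2 fold change of 1.87 that became 3.33 without replicate 3; Vil1 had a fitted fold of 1.35 (adjusted p = 0.0841). Of 20 epithelial identity genes, 0 changed over all genes and 1 rose when adjusted over the list alone, with Krt7 at 0.34 and Cldn18 at 0.93 on the log2 scale (adjusted p = 0.0526 and 0.120). Of 8 epithelial-mesenchymal transition genes, 0 changed, also adjusted over the list alone; Fn1 stood at 0.57 (SE 0.18) and Plaur at 0.24. The last 2 lists passed camera as higher (adjusted p = 0.0107 and 0.0121), with an adjusted p of 0.146 and 0.269 with an estimated correlation.

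Of 11 fibroblast, 12 immune cell and 9 endothelial markers, 2, 2 and 3 had enough counts to be tested, and 0 differed over all genes (0, 1 and 1 when adjusted over the list alone). The remaining members reached at most 0.583 CPM in any library. Fbln1 was at 69.1 ± 22.1 CPM in controls and 74.2 ± 19.4 CPM in overexpressing organoids, Col1a1 at 0.855 ± 0.504 and 1.24 ± 0.145 CPM, Cd68 at 31.3 ± 18.9 and 41.6 ± 28.4 CPM, Ptprc at 1.40 ± 0.625 and 0.758 ± 0.293 CPM, Tek at 0.501 ± 0.314 and 3.08 ± 5.08 CPM, and Esam at 3.04 ± 1.83 and 3.52 ± 1.40 CPM (SD, n = 3).

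In the genes of antigen presentation and immune signalling, 2 of 18 MHC class I presentation genes rose, and 4 rose and 1 fell when adjusted over the list alone. B2m, the light chain of class I molecules, rose 1.30-fold from 177 ± 83.0 CPM to 224 ± 76.0 CPM (adjusted p = 0.0317), and the class I gene H2-T23 rose 1.49-fold, with reads that similar class I genes can share. The chaperone gene Calr had a log2 fold change of -0.32 (SE 0.08, adjusted p = 0.0594) and the peptide transporter gene Tap1 one of 0.55 (SE 0.16). The list did not pass camera (adjusted p = 0.207). Of 9 MHC class II genes 2 were tested and 0 changed, also adjusted over the list alone, with Cd74 at 1.08 ± 1.56 CPM in controls and 0.667 ± 0.136 CPM in overexpressing organoids and H2-DMa at 0.747 ± 0.386 and 0.771 ± 0.562 CPM. The remaining members reached at most 1.12 CPM. With no filter on low counts the class II list passed camera as lower without the block (adjusted p = 0.0467) and not with it (0.172). Of 23 interferon response genes, 0 changed, also adjusted over the list alone; Bst2 had a log2 fold change of 0.53 (SE 0.17, adjusted p = 0.137) and Xaf1 one of 0.91. This list passed camera as higher with an adjusted p of 0.0296, against an adjusted p of 0.551 with an estimated correlation. It did not pass with no filter on low counts (0.0808, or 0.0536 with the block) or, with the block, on voom values (0.0587).

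Of 14 immune checkpoint ligands and related surface proteins, 1 rose, also when adjusted over the list alone with and without the block. This was Ceacam1, an adhesion molecule that binds inhibitory receptors, which rose 1.62-fold from 65.0 ± 11.9 CPM to 104 ± 7.07 CPM (adjusted p = 0.00203); its close paralog can share reads. Cd274, which encodes PD-L1, was near the limit of detection at 0.485 ± 0.317 CPM in controls and 0.961 ± 0.472 CPM in overexpressing organoids (adjusted p = 0.527). Pvr had a log2 fold change of 0.22, Lgals9 of -0.08, Cd276 of 0.11, Vtcn1 of 0.02, Cd47 of -0.01 and Nectin2 of 0.01, each with an adjusted p between 0.414 and 0.973. The list passed camera as higher without the block (adjusted p = 0.0253) and not with it (adjusted p = 0.0563), and the adjusted p was 0.176 with an estimated correlation. Without the block it did not pass with a filter of at least 1 CPM in 3 libraries (0.0517), and with the block it passed with no filter on low counts (0.0283) or with offsets for GC content and length (0.0370). Of 22 chemokines and cytokines, 3 rose, and 8 rose and 1 fell when adjusted over the list alone. The alarmin Il33 rose 1.92-fold, the chemokine Ccl20 1.72-fold and Csf2, which encodes GM-CSF, 2.66-fold from 1.54 ± 0.608 CPM to 4.25 ± 1.16 CPM (log2 fold change 1.41, or 2.03 without replicate 3), while Lif had a log2 fold change of 0.74 (adjusted p = 0.0516). The camera adjusted p of this list was 7.17e-07, against an adjusted p of 0.146 with an estimated correlation.

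**Figure D3:**
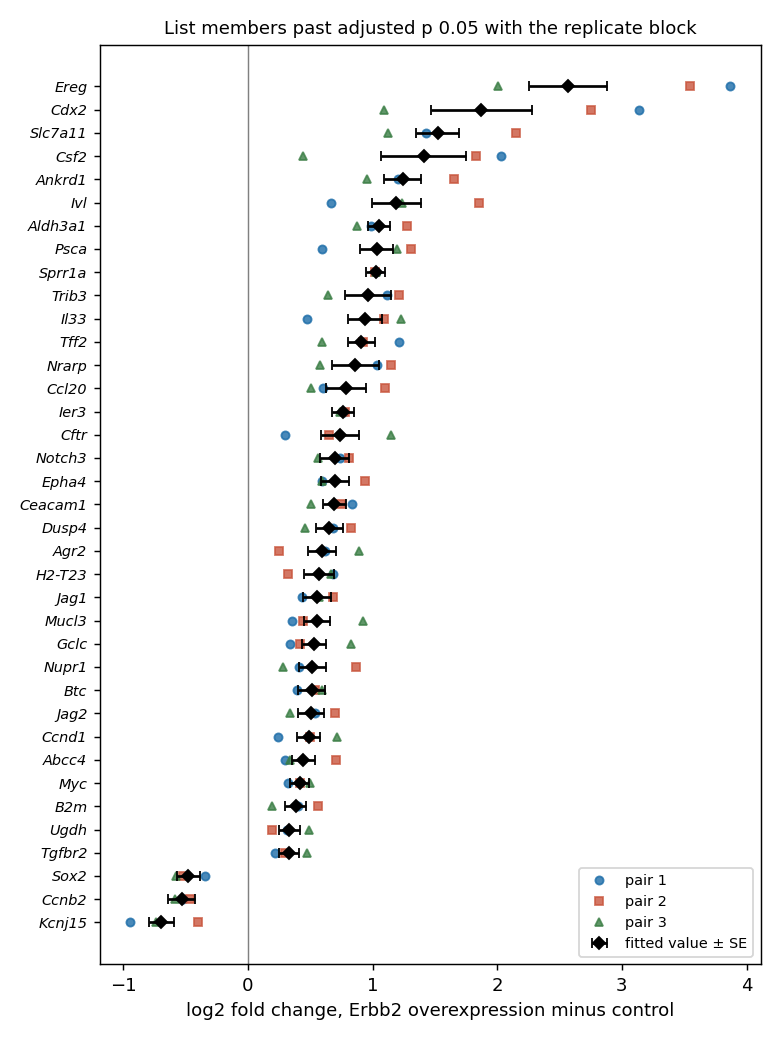
Log2 fold change of Erbb2 overexpression over control (horizontal axis) for the 37 list genes that passed an adjusted p of 0.05 with the replicate block, at most 4 per list, with diamonds and bars for the fitted value and its standard error and coloured symbols for the 3 pairs of libraries. All 3 pairs lie on the same side of 0 for every gene plotted, with 34 genes above 0 and 3 below. The genes were chosen by the fit to these pairs, which favours such agreement.

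Of 16 NRF2 targets, 4 rose and 5 when adjusted over the list alone (2, Slc7a11 and Gclc, without the block). Slc7a11, the cystine transporter gene, rose 2.87-fold from 23.7 ± 10.7 CPM to 66.3 ± 19.1 CPM, Gclc, the catalytic subunit of glutamate-cysteine ligase, 1.44-fold, Abcc4 1.36-fold and Ugdh 1.26-fold (camera, adjusted p = 0.000265, or adjusted p = 0.176 with an estimated correlation). Of 9 Notch pathway genes, 4 rose and 5 when adjusted over the list alone. The receptor gene Notch3 rose 1.62-fold, the ligand genes Jag1 and Jag2 1.47-fold and 1.42-fold, and the target gene Nrarp 1.82-fold (camera, adjusted p = 0.00165, or adjusted p = 0.146 with an estimated correlation). Of 14 YAP targets, 1 rose, also when adjusted over the list alone with and without the block: Ankrd1, 2.36-fold from 10.5 ± 3.11 CPM to 24.7 ± 2.54 CPM, beside Amotl2 at a log2 fold change of 0.25. The YAP list passed camera with the block (adjusted p = 0.0266) and not without it (adjusted p = 0.0549), with an adjusted p of 0.506 with an estimated correlation and the block. With the block it did not pass without replicate 3 (adjusted p = 0.445) or with offsets for GC content and length (adjusted p = 0.128), and without the block it passed when control replicate 1 or Erbb2 replicate 2 was left out (adjusted p = 0.00283 and 0.0389). Of 17 gastric cancer driver genes, 2 rose, and 4 when adjusted over the list alone: Myc, above, and the TGF-beta receptor gene Tgfbr2, 1.26-fold (adjusted p = 0.0446). Trp53, Cdh1, Arid1a and Pik3ca had log2 fold changes between -0.04 and 0.01. Of 16 unfolded protein response genes, 1 rose, Trib3, 1.95-fold, and 6 rose and 2 fell when adjusted over the list alone; Chac1 stood at 0.88 on the log2 scale (adjusted p = 0.108).

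Of 25 mitosis genes, 1 fell, the cyclin gene Ccnb2, by a log2 fold change of -0.53 (SE 0.11, adjusted p = 0.0202), and 13 fell when adjusted over the list alone. All 25 fitted values were below 0, with a median of -0.36 with the block; Plk1 stood at -0.48 (adjusted p = 0.0574). The medians of the pairs were -0.26, -0.01 and -0.71 for replicates 1, 2 and 3. The list passed camera as lower (adjusted p = 0.000101), with an adjusted p of 0.551 with an estimated correlation, and without control replicate 3 its median was 0.18 (adjusted p = 0.393). Of 25 DNA replication genes, 0 changed, also adjusted over the list alone, with Cdc45 at -0.52 (SE 0.15, adjusted p = 0.0850) and Rrm1 at -0.28. This list passed camera as lower (adjusted p = 0.0365), with an adjusted p of 0.806 with an estimated correlation and 0.0893 on voom values, and without control replicate 3 it passed as higher (adjusted p = 0.0126). Of 19 p53 targets, 0 changed, also adjusted over the list alone, with Tnfrsf10b at 0.30 and Sesn2 at 0.32. The p53 list passed camera as higher (adjusted p = 0.00344), against an adjusted p of 0.489 with an estimated correlation. Of 20 hypoxia and glycolysis and 20 cholesterol synthesis genes, 0 and 0 changed, also adjusted over the list alone. Hk2 stood at 0.24, Adm at -0.41, Fdps at -0.19 and Hmgcs1 at -0.20 on the log2 scale, and with all libraries neither list passed camera (adjusted p = 0.973 and 0.161). Without control replicate 2 or Erbb2 replicate 3 the cholesterol list passed as lower (adjusted p = 8.12e-06 and 0.00617), as it did with the block without replicate 2 (0.0313). The hypoxia list passed as lower without control replicate 1 or Erbb2 replicate 3 (0.0249 and 0.00082) and as higher without control replicate 3 (0.000307).

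Over the 29 lists tested, camera placed 13 higher and 2 lower without the block, and 14 higher and 2 lower with it. None passed with an estimated correlation, where 7 lists had an unadjusted p under 0.05 without the block and 3 with it, and none passed the rotation test fry, where 6 and 9 did. The power of either test with 3 libraries per group was not measured, so that a miss there does not show that a list is unchanged. Leaving out a single library ended the call without a block of 8 lists. Without Erbb2 replicate 2 the adjusted p was 0.363 for pit cells, 0.0824 for mitosis, 0.626 for DNA replication, 0.0668 for epithelial identity and 0.0639 for checkpoint ligands. It was 0.0902 for DNA replication and 0.0852 for interferon response without Erbb2 replicate 1, and 0.402 for p53 targets and 0.120 for epithelial-mesenchymal transition without Erbb2 replicate 3. Without control replicate 1 it was 0.121 for epithelial identity, 0.739 for interferon response and 0.146 for checkpoint ligands, without control replicate 2 it was 0.371 for interferon response and 0.130 for epithelial-mesenchymal transition, and without control replicate 3 it was 0.526 for pit cells. Leaving out a single library also added calls without a block, beyond those given above. Chief cell markers passed as lower without control replicate 1 or Erbb2 replicate 3 (0.00475 and 0.0197), Wnt and stem cell genes as lower without control replicate 2 (0.000429), and unfolded protein response genes as higher without Erbb2 replicate 2 (0.0433). With the block, chief cell markers passed as lower without replicate 1 (0.0150), Wnt and stem cell genes as lower without replicate 2 (0.00101), and intestinal genes and checkpoint ligands as higher without replicate 3 (0.0454 for both). With the block, leaving out a pair ended the call of interferon response (adjusted p = 0.829 without replicate 1 and 0.243 without replicate 2), epithelial-mesenchymal transition (0.0713 without replicate 1), and DNA replication and p53 targets (0.455 and 0.515 without replicate 3).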

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

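The fits with both the block and another change were chosen after the data were seen. Without a block, the counts of 0 genes higher and 0 lower stayed at 0 under both other scalings, both other filters, limma voom, the earlier quasi-likelihood fit and removal of mitochondrial genes and Erbb2. DESeq2 called 28 higher and 6 lower (16 and 6 at least 2-fold) and Erbb2 at a log2 fold change of 1.23; 31 of these 34 genes are among the 389 called with the block. The replicate block gave 298 higher and 91 lower (79 and 27 at least 2-fold) and Erbb2 at 1.24; by construction the block takes out the spread between replicate numbers. Leaving out 1 library gave 0 to 1 genes higher, 0 to 1 at least 2-fold higher, and 0 to 5 lists lower; the single gene was Mgam2-ps, without control replicate 3. Lists lower numbered 0 without Erbb2 replicate 2, 1 without Erbb2 replicate 1 or control replicate 3, 4 without control replicate 1 or 2, and 5 without Erbb2 replicate 3. With an estimated correlation 0 lists were higher and 0 lower, with fry 0 and 0, and camera on voom values left 1 lower and ended the call of pit cell markers. The block ended the call of checkpoint ligands, added those of parietal markers and YAP targets, which other settings with the block end in turn, and changed no other list. Filters, offsets or voom values also changed calls of checkpoint ligands, interferon response and, with the block, Wnt and stem cell genes. With no filter on low counts, camera also called the MHC class II list lower without the block (adjusted p = 0.0467) and not with it (0.172). Where the turned direction or the original one was past the threshold, the direction of camera turned for hypoxia and glycolysis without control replicate 1 (median log2 fold change -0.25) or Erbb2 replicate 3 (-0.38, range over left-out libraries to 0.50), and without control replicate 3 for AP-1 genes (-0.33, range -0.44 to 0.47), DNA replication (0.22, from -0.44) and mitosis (0.18, from -0.74). The hypoxia and AP-1 medians with all libraries were -0.03 and -0.01, against a camera direction of higher, so for these the test turned and not the median. Directions not past the threshold on either side, such as those of cholesterol and chief cell genes without control replicate 3, also turned. With the block, DNA replication turned without replicate 3 (0.037, not past the threshold). With the block, leaving out a pair gave 122 to 769 genes higher, 24 to 320 lower, 50 to 219 and 7 to 47 at least 2-fold, and 1 to 4 lists lower; the lowest counts came without replicate 2, except 50 without replicate 1 and the 1 list without replicate 3, and the highest without replicate 3, except the 4 lists without replicate 2. Of the 389 calls, 371 were kept without replicate 3, 178 without replicate 1 and 120 without replicate 2. Fewer libraries also mean less power, so that these shifts do not measure dependence on a pair alone. With the block, an estimated correlation gave 0 lists higher and 0 lower, and so did fry. Other alternatives with the block kept each count within 1.5 times, and the 49 named genes called besides Erbb2 kept their direction in all 588 of their blocked alternatives, 527 of them past the threshold and 61 not. The causes were not tested otherwise. Depth limits the low genes: at 18735853 to 22767455 counts, Cd274, under 1 CPM in the mean of each group, rests on few counts per library.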

Other observations

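The tests of squamous cells and of a single pair behind the mitosis list, and the comparison of replicate numbers, were chosen after the results were seen. Apart from the genotype, 3648 of the 12593 genes (29.0%) differed between the replicate numbers (edgeR with the block, F test of the number terms, adjusted p under 0.05). In the hypoxia and glycolysis list 19 of 20 genes differed, and all 19 were highest in replicate 3. The lactate transporter gene Slc16a3 averaged 18.0, 15.4 and 73.1 CPM in the control and Erbb2 libraries of replicates 1, 2 and 3, and Bnip3 24.2, 21.9 and 85.8 CPM. In the mitosis list 22 of 25 differed, each highest in replicate 3, with Ccnb2 at 19.5, 15.9 and 45.3 CPM and Ube2c at 22.8, 19.2 and 61.5 CPM; in DNA replication 17 of 25 differed in the same way. Of 16 AP-1 and immediate early genes 15 differed and 14 were lowest in replicate 3, with Atf3 at 64.2, 124 and 7.72 CPM and Egr2 at 45.5, 92.9 and 6.31 CPM. Of 13 pit cell markers 9 differed and 8 were lowest in replicate 3, with Mucl3 at 494, 915 and 58.7 CPM. The chief cell gene Gif, which encodes intrinsic factor, averaged 3.55, 1.33 and 35.1 CPM. The labels do not say what the numbers stand for, and no explanation was tested.

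The first pattern weighed is that 76.6% of the 389 genes called with the block were higher in Erbb2 overexpression. The choice among the scalings tried is argued against, since under relative log expression, under upper-quartile scaling and without mitochondrial genes and Erbb2 the share stayed at 75.6% or more. All of them centre on the bulk of genes. The median log2 fold change of all genes was -0.007 under TMM, -0.001 under relative log expression and -0.007 under upper-quartile scaling. A scaling error common to these methods could not be seen in this way. GC content or transcript length bias is argued against as the whole cause, since 85.3% of the calls were kept in the same direction with offsets for both, with 267 higher and 120 lower. A gained or lost chromosome or large segment is argued against, since the highest median log2 fold change that all 3 pairs shared over chromosomes and runs of 50 neighbouring genes was 0.097. As a hypothesis, the excess of higher genes may be a response to the construct, and a difference between the cultures other than the construct stays open, since neither was tested.

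The second pattern is the rise of the squamous forestomach genes Sprr1a and Ivl. Basal squamous cells from the forestomach are argued against. Krt5 and Krt14, the abundant basal keratins of that epithelium, together rose by at most 0.105% of the rise of Sprr1a in any pair. They reached 0.458 CPM at most in an overexpressing library. Squamous cells without basal ones would not be seen in this way and stay open. Of the 17 list genes 9 were expressed well enough to be tested in these organoids, among them Krt4 at 225 ± 29.9 CPM in controls. As a hypothesis, the rise may lie in the gastric epithelial cells themselves, and which cells express these genes was not tested.

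The third pattern is the lower mitosis list, which camera called at a preset correlation and not at an estimated one (adjusted p = 0.551, or 0.506 with the block). GC content or transcript length bias is argued against, since with offsets for both the median log2 fold change with the block stayed at -0.34. Whether a single pair carries the difference cannot be told apart from a shared decrease. Without replicate 3 the median was -0.15 with a camera adjusted p of 0.0180 at the preset correlation, but the median of pair 2 was -0.01. The genotype and a difference in culture state between the libraries of replicate 3 both stay open.

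Other splits of the 6 libraries were compared with the real one. Without a block all 10 splits gave 0 genes and 0 genes changed at least 2-fold, so that 10 of 10 were as large as the real split. The real split gave 15 gene lists and the highest other split 11, so that 1 of 10 was as large. With the block, 4 splits part all 3 pairs. The real one gave 389 genes, 106 of them at least 2-fold changed, and 16 lists, and the highest of the other 3 gave 0 genes, 0 at least 2-fold changed and 12 lists, so that 1 of 4 was as large in each. The other 3 exchange the labels within 1 pair each and keep the real labels in the remaining pairs. The other splits without a block also hold unequal numbers of each group on each side. Part of the real difference therefore stays in all of them. With 10 or 4 splits a share under 0.05 cannot be reached.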
